A study of Homo sapiens with 6 samples.

How the data were processed

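RNA was measured in 6 cultures of KOLF2-C1, an established human induced pluripotent stem cell line, which had been taken through a chemically defined protocol for making brown adipocytes. The culture was sampled at day 50 (3 libraries) and day 60 (3 libraries). Per the labels' protocols, RNA was extracted with a column kit and poly(A)-selected before fragmentation, cDNA synthesis and ligation with an NEB Ultra II kit. Libraries carried unique dual indexes and were pooled in equal amounts. The labels call the libraries biological replicates but do not say whether each came from its own differentiation, so p-values measure the spread between these libraries.

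The deposited table holds raw counts, which are whole numbers of reads per gene without normalization, for 19968 genes named by Ensembl identifier and symbol. Per the submitters' processing notes, the tools were cutadapt 2.10, STAR 2.7 and featureCounts 1.6.2 from the Subread package, with genome build GRCh38.p12. The strand setting, the treatment of reads that map to several places and the annotation release are not given in the sources used here. Genes that share reads with a near-identical copy, such as ribosomal protein genes with processed pseudogenes or CKMT1A and CKMT1B, are therefore uncertain, as are overlapping and antisense genes. All 13 mitochondrially encoded genes were listed at 0 in every library, so they carry no information on mitochondrial RNA in these cells. In the deposited count table, 50 symbols had been changed to currency amounts by a spreadsheet (DKK3 is an example), and 46 of them added a field to their row. The counts were read as the last 6 fields of each row, and all 50 names were recovered from the Ensembl identifiers. Of the identifiers, 19899 were found in GENCODE release 29 on GRCh38, 19874 of them as protein coding, and 69 were not. Coordinates are from that release and need not be those of the authors' annotation.

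Libraries held between 54385277 and 70547432 counts. A count of 0 in a library allows a level of up to 3 counts, which is between 0.0425 and 0.0552 CPM by library, where CPM is the count scaled to a fixed library total. These floors cover counting error only, since reads without molecular identifiers are not independent molecules. The low-count filter of edgeR (filterByExpr with its defaults, minimum count 10 and minimum total 15) left 15577 genes and set aside 4391, of which 1652 were at 0 in all libraries. The tested genes held at least 99.979% of the counts of every library. Levels are CPM after scaling by trimmed mean of M values (TMM, factors from 0.9513 to 1.069), computed from the deposited counts, with mean and SD over the 3 libraries of a day.

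Day 60 was compared with day 50 by the quasi-likelihood F test of edgeR 4.0.16 in R 4.3.3, two-sided, over all 6 libraries without covariates, with Benjamini-Hochberg adjustment and a threshold of 0.05. Log2 fold changes are day 60 over day 50 and are given ± SE, and intervals are at the 95% level. There were 44 gene lists, for adipocyte, progenitor, metabolic, stress, signalling and RNA quality genes and for markers of other cell types. The 43 lists with at least 5 tested members were tested with camera from limma 3.58.1, which compares the members of a list with all other genes. It ran on log2 CPM with voom weights and a preset correlation between genes of 0.01. The same lists were tested with a correlation estimated per list and with fry. Libraries were compared by principal components of log2 CPM (prior count 2), by the correlation across genes of each pair, and by the biological coefficient of variation (BCV) of each pair, which is the spread between libraries left after counting noise.

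The lists, the tests, the other settings to be tried and the rule for naming genes were fixed before the data were examined. The rule took the 10 genes with the largest change each way among called genes that separated the days at a mean of at least 5 CPM in the higher day, and there were none. It took up to 4 members of each called list with the smallest adjusted p in the direction of the list, with ties broken by unadjusted p. It also took a fixed set of 22 adipocyte, progenitor, proliferation, pluripotency and muscle genes, and the 2 most abundant members of each list for another cell type. Some genes that the rule takes are not reported here. Genes chosen after their values were seen are named as such. Alternatives were 3 other normalizations, 2 other filters, DESeq2 1.42.0, limma voom, a replicate block, a stricter threshold, a fold threshold, leaving out each library in turn, and leaving out abundant or mitochondrially encoded genes.

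The gene test was checked on simulated counts drawn from the means, dispersions and library sizes of this comparison, with 200 of the 15577 genes changed in each of 5 simulations. It called 2.8% of genes changed 2-fold, 49.2% of those changed 4-fold, 73.2% of those changed 8-fold and 86% of those changed 16-fold, and 43 of 76790 unchanged genes. In the same simulations a list shifted 2-fold was called by camera in 5 of 5, and 0 of 210 other list tests were called. Simulated genes were independent of each other and real genes are not. Simulated libraries were also drawn independently around the mean of their day, without the structure across days that the real libraries had.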

Results

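The expression of protein-coding genes was measured by poly(A) RNA sequencing in KOLF2-C1 cells, a human induced pluripotent stem cell line, on day 50 (n = 3 libraries) and day 60 (n = 3 libraries) of differentiation toward brown adipocytes, the thermogenic fat cells that burn fuel through the uncoupling protein UCP1. The day 60 profile served the study as the input of a computational search for small molecules that help mesodermal progenitors become mature brown adipocytes, and day 50 was measured for comparison. The day 50 libraries held 61177282, 58466794 and 66220224 counts for replicates 1, 2 and 3. The day 60 libraries held 54385277, 70547432 and 66085801. Levels are CPM, which are TMM-normalized read counts scaled to a common library total.

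Extracellular matrix genes were among the most abundant transcripts of these cultures at both days. COL1A1, which encodes a chain of type I collagen (chromosome 17, 50183289 to 50201632, minus strand, GRCh38, ENSG00000108821), stood at 17100 ± 4053 CPM on day 50 and 19210 ± 4490 CPM on day 60 (SD, n = 3). COL3A1, a type III collagen gene chosen after the values were seen, was the most abundant gene at day 60 with 24130 ± 8028 CPM. PDGFRA, a receptor of mesenchymal progenitors, was at 200.1 ± 109.3 CPM on day 50 and 264.4 ± 71.4 CPM on day 60. DLK1, a preadipocyte factor that is lost as adipocytes mature and was also chosen after the values were seen, was at 4073 ± 2140 and 3971 ± 1933 CPM.

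The markers of mature and thermogenic adipocytes in the fixed set that are named here were low or near the detection floor at both days. Not all genes of the adipose lists were low. Among members chosen after the values were seen, CKB was at 829.3 and 841.7 CPM on days 50 and 60, ACSL1 at 226.1 and 249.6 CPM and PNPLA2 at 62.5 and 72.6 CPM. UCP1 (ENSG00000109424, chromosome 4, 140559434 to 140568805, minus strand) had 7, 11 and 2 reads in the day 50 libraries and 2, 5 and 20 in the day 60 libraries, at most 0.31 CPM, too few to pass the count filter. CIDEA, a lipid droplet gene typical of brown fat, had 2 reads in day 60 replicate 3 and 0 in the other 5 libraries. ADIPOQ, which encodes the adipocyte hormone adiponectin (ENSG00000181092, chromosome 3, 186842690 to 186858463, plus strand), had 1 read in day 50 replicate 2 and 0 in the other 5. LEP, which encodes leptin, had 1 read in day 50 replicate 1, 3 in day 60 replicate 3 and 0 in the other 4. The brown fat regulators PPARGC1A and PRDM16 were measurable. PPARGC1A was at 1.79 ± 0.547 CPM on day 50 and 1.63 ± 0.465 CPM on day 60, and PRDM16 at 0.742 ± 0.115 and 0.935 ± 0.248 CPM. The deiodinase gene DIO2 was at 0.418 ± 0.393 and 0.71 ± 0.195 CPM, and EBF2, a transcription factor of the brown fat lineage, at 0.698 ± 0.544 and 0.51 ± 0.536 CPM. ADRB3, the adrenergic receptor through which fat is activated, ranged from 0.5 CPM in day 50 replicate 2 to 6.58 CPM in day 60 replicate 2.

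The general adipocyte regulators PPARG and CEBPA stood higher. PPARG, the master regulator of fat cell formation (ENSG00000132170, chromosome 3, 12287368 to 12434356, plus strand), was at 18.1, 6.66 and 6.88 CPM in the day 50 libraries and 17.9, 7.87 and 9.98 CPM in the day 60 libraries. Its log2 fold change of 0.18 ± 0.50 (SE) was smaller than the spread within a day. CEBPA, its partner, was at 12.5 ± 1.17 CPM on day 50 and 14.9 ± 1.17 CPM on day 60, with a log2 fold change of 0.25 ± 0.21. FABP4, a fatty acid carrier of adipocytes, went from 0.1 CPM to 6.15 CPM within day 50 and from 0.27 to 3.46 CPM within day 60. The lipid droplet coat gene PLIN1 was at 3.14 ± 1.62 and 3.34 ± 1.75 CPM. No member of either adipocyte list passed the test, adjusted over all genes or adjusted over the list alone.

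**Figure D1:**
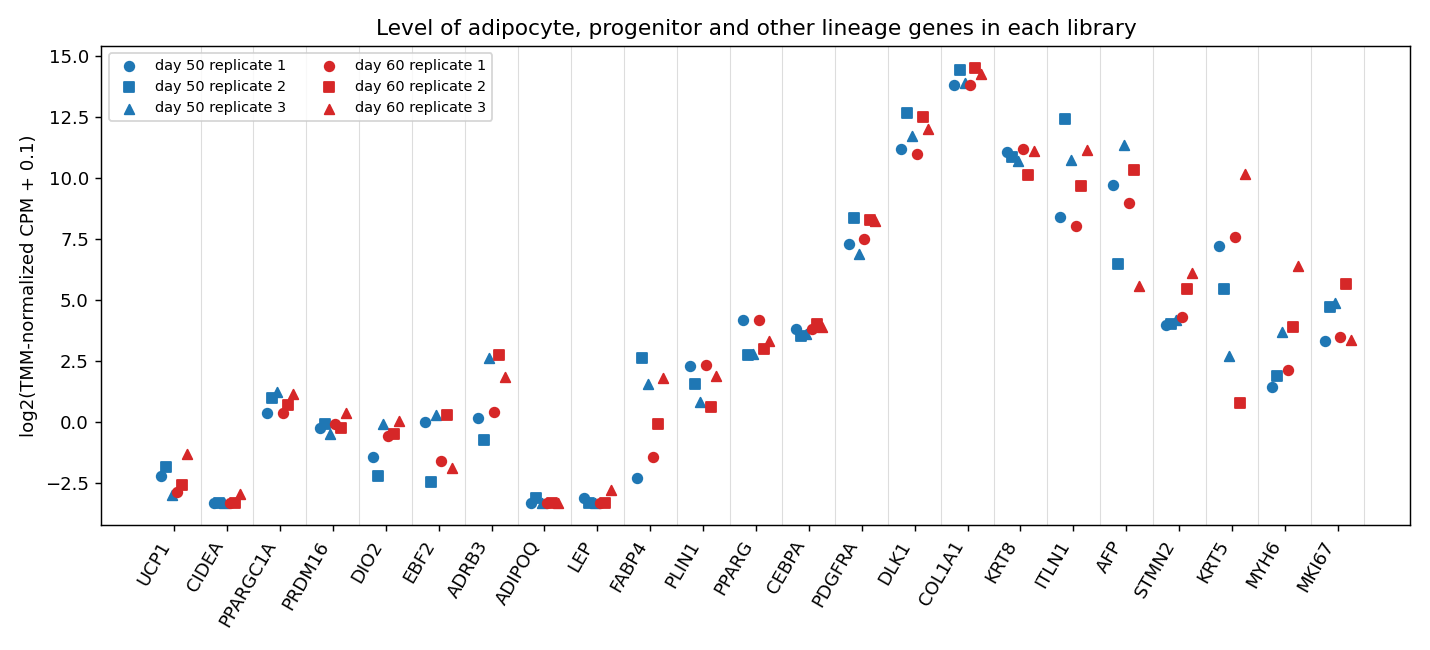
Levels of adipocyte, progenitor and other lineage genes in each library, as log2 of TMM-normalized CPM plus 0.1, with day 50 in blue, day 60 in red and symbols for replicates. UCP1, CIDEA, ADIPOQ and LEP lie at the bottom of the scale in all 6 libraries, and AFP and KRT5 spread over the widest ranges, from 48.25 to 2590 CPM and from 1.64 to 1135 CPM.

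The comparison of day 60 with day 50 asks what changes over the last 10 days of the protocol. No gene was called higher and no gene lower at day 60 (edgeR quasi-likelihood test, 0 of 15577 genes, smallest adjusted p = 0.99996). At an unadjusted p under 0.05 there were 104 genes, 61 higher and 43 lower. That is 0.668% of those tested, below the share of 0.05 that chance gives. DESeq2 and limma voom also called 0 genes, with 254 and 99 at an unadjusted p under 0.05. Of all tested genes, 207 were higher in every day 60 library than in every day 50 library and 255 were lower in every one, together 2.97%, where chance gives 10%. Both chance shares assume that the libraries are grouped by nothing but day, and these libraries were grouped across the days. In edgeR, other splits of the 6 libraries into equal groups gave 139 to 4974 genes at an unadjusted p under 0.05. The low shares therefore do not show that the days were more alike than chance. The 95% interval of a log2 fold change reached 0.755 to either side of its estimate in the median gene. For 8268 genes, 53.1% of those tested, the interval excluded a 2-fold change in either direction. For the others a change of that size was not excluded by these 6 libraries.

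Among the genes that a brown adipocyte program would name, the brown thermogenic list had 16 of 29 tested members with a positive fitted change. Its median log2 fold change was 0.04 and its mean 0.02, while camera placed it lower (adjusted p = 0.893), or higher when libraries were scaled by total count only (adjusted p = 0.895). Camera also placed it higher without day 50 replicate 1 (adjusted p = 0.785) or without day 60 replicate 2 (adjusted p = 0.427). The general adipocyte list had 23 of 33 members with a positive change and a median of 0.10 (camera, adjusted p = 0.132). The progenitor and preadipocyte list had 18 of 25, with a median of 0.22 (adjusted p = 0.173), and fatty acid oxidation 16 of 27, with a median of 0.06 (adjusted p = 0.489). None of these 4 lists passed with all libraries. The general adipocyte list passed without day 50 replicate 1 (0.0163), day 60 replicate 2 (0.00288) or both replicate 1 libraries (0.0419), and its adjusted p was 0.949 without day 50 replicate 3, where its direction turned. The progenitor list passed without day 50 replicate 2 (0.0235) or day 60 replicate 1 (0.00497) and with a filter of CPM above 1 (0.0379), and without day 60 replicate 3 its adjusted p was 0.83 with the direction turned. With an estimated correlation their adjusted p-values were 0.882 and 0.821.

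Of the 43 lists tested, 13 passed camera with the preset correlation, 11 of them higher and 2 lower at day 60. With the correlation estimated for each list 0 of 43 passed, the smallest adjusted p being 0.613 and 2 lists having an unadjusted p under 0.05. A higher correlation cannot account for every call lost in this way. The beige and early mesoderm lists had estimated correlations of -0.02 and -0.041, below the preset 0.01. Their unadjusted p in camera still rose from 0.0102 to 0.0564 and from 0.0014 to 0.0285. With an estimated correlation camera also judges its statistic by the small number of libraries rather than by the number of genes. Calls lost in this way therefore do not measure correlation between genes alone. The rotation test fry called 0 lists, with 0 at an unadjusted p under 0.05 and a smallest adjusted p of 0.971. The count also rested on single libraries, since 2 lists passed without day 60 replicate 3 and 8 without day 50 replicate 2. Of the 10 splits of the libraries into equal groups, 7, the real one included, called at least 13 lists with the preset correlation. The highest other count was 20. The list calls described below therefore do not set the day apart from other groupings of these libraries.

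Neuronal genes gave the largest median change of the 43 lists. All 19 tested members had a positive fitted change, with a median log2 fold change of 1.10, and 4 of them were higher in every day 60 library than in every day 50 library (camera adjusted p = 5.97e-13). With an estimated correlation its adjusted p was 0.613. STMN2, a microtubule regulator of growing axons (ENSG00000104435, chromosome 8, 79610814 to 79666175, plus strand), was at 15.9, 16.0 and 18.3 CPM on day 50 and 19.6, 43.2 and 68.5 CPM on day 60, a log2 fold change of 1.39 ± 0.43. The other named members were the RNA-binding protein gene ELAVL4, at 2.81 ± 0.79, and the neurofilament genes INA, at 2.05 ± 0.63, and NEFL, at 1.88 ± 0.69. Their unadjusted p-values in edgeR were 0.00913, 0.0144 and 0.0302, and none passed after adjustment. ELAVL4 was at mean levels of 0.158 CPM on day 50 and 1.12 CPM on day 60, and INA at 0.657 and 2.72 CPM. NEFL stood at 1.93 and 7.08 CPM. ELAVL4 had 6, 13 and 11 reads on day 50 and 13, 99 and 113 reads on day 60. NCAM1, which with STMN2 was the most abundant member, was at 130.4 CPM in day 60 replicate 2 and at 33.6 to 75.0 CPM in the other libraries. The day 50 libraries themselves differed, and day 60 replicate 1 stood above day 50 replicates 2 and 3 but not above day 50 replicate 1. Relative to the mean of the 6 libraries, the list median was -0.02, -0.67 and -0.62 in day 50 replicates 1, 2 and 3. It was -0.04, 0.97 and 0.42 in day 60 replicates 1, 2 and 3.

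Lists of energy metabolism and translation were higher by small amounts. All 75 cytosolic ribosomal protein genes had a positive fitted change with a median of 0.21 (camera adjusted p = 5.97e-13, and adjusted p = 0.821 with an estimated correlation). Without day 50 replicate 3 the call was lost at an adjusted p of 0.509. Ribosomal protein genes took 4.84% of the counts in that library, 7.45% in day 60 replicate 3 and between 6.34% and 6.61% in the other 4. RPS28 and RPL38, which encode proteins of the small and the large ribosomal subunit, had log2 fold changes of 0.40 ± 0.26 and 0.35 ± 0.26. Of 77 nuclear genes of oxidative phosphorylation 74 had a positive change, with a median of 0.21 (adjusted p = 1.98e-08, and adjusted p = 0.821 with an estimated correlation). CYC1, NDUFS4, ATP5F1D and COX8A, which encode subunits of respiratory complexes, were at 0.35 ± 0.20, 0.30 ± 0.19, 0.39 ± 0.26 and 0.39 ± 0.26. Glycolysis genes had 17 of 18 positive, with a median of 0.27 (adjusted p = 0.00211, and adjusted p = 0.821 with an estimated correlation). The hexokinase gene HK1 was at 0.37 ± 0.21 and GPI at 0.41 ± 0.29. The TCA cycle list had 19 of 22 positive, with a median of 0.10 (adjusted p = 0.0337, and adjusted p = 0.821 with an estimated correlation). PC and MDH2 were at 0.33 ± 0.24 and 0.18 ± 0.17. Without day 60 replicate 3 none of these 3 metabolic lists passed, at adjusted p-values of 0.818 for oxidative phosphorylation, whose direction turned, 0.956 for glycolysis and 0.477 for the TCA cycle. Glycolysis was also lost without day 50 replicate 2 (0.654). The TCA cycle was also lost without day 50 replicates 2 or 3 (0.206 and 0.16) or day 60 replicate 1 (0.417), and with no count filter (0.0561). The 13 genes of the mitochondrial genome were listed at 0 and could not be tested.

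Muscle and mesoderm lists were also higher. Skeletal muscle genes had 13 of 19 members with a positive change and a median of 0.78 (camera adjusted p = 0.00678, and adjusted p = 0.821 with an estimated correlation). The intermediate filament gene DES was at 152.3 ± 48.2 CPM on day 50 and 272 ± 126 CPM on day 60, a log2 fold change of 0.84 ± 0.41. The creatine kinase gene CKM was at 2.53 ± 1.08, and the myosin genes MYH3 and MYH7 at 2.22 ± 1.04 and 1.08 ± 0.45. CKM stood at 10.1 CPM in day 60 replicate 3 and at 0.40 to 1.93 CPM elsewhere. MYH3 stood at 5.05 CPM in day 60 replicate 2 and at 0.24 to 0.64 CPM elsewhere. Of the named genes, DES, CKM and MYH7 are also expressed in heart. The heart myosin gene MYH6, chosen after the values were seen, was at 2.42 ± 1.11. The cardiac list had 9 of 14 members positive and did not pass (camera adjusted p = 0.82). The myogenic regulators did not stand with the named skeletal muscle genes, as MYOD1, MYOG, PAX3 and PAX7 were at or below 0.33 CPM in each library. Smooth muscle genes had 16 of 17 positive with a median of 0.41 (adjusted p = 0.0272, and adjusted p = 0.821 with an estimated correlation). TAGLN was at 618.9 CPM in day 60 replicate 3 and at 69.1 to 206 CPM elsewhere, a log2 fold change of 1.05 ± 0.80, and LMOD1 was at 0.49 ± 0.24. Early mesoderm genes had 10 of 11 positive with a median of 0.38 (adjusted p = 0.00858, and adjusted p = 0.613 with an estimated correlation). PRRX1 was at 1.40 ± 1.08, FOXC2 at 1.54 ± 0.91 and TWIST1 at 0.38 ± 0.35. PRRX1 stood at 30.1 CPM in day 60 replicate 2 and at 1.14 to 8.68 CPM elsewhere. FOXC2 stood at 4.06 CPM in day 60 replicate 3 and at 0.35 to 1.14 CPM elsewhere. The skeletal and smooth muscle calls were each lost without day 50 replicate 1 or 2 or day 60 replicate 2 or 3. The adjusted p-values were then 0.08, 0.0839, 0.328 and 0.102 for skeletal muscle and 0.658, 0.102, 0.27 and 0.877 for smooth muscle, the last with its direction turned. The early mesoderm call was lost without day 50 replicate 1 (0.0601) or day 60 replicates 2 or 3 (0.163 and 0.102).

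A further 3 lists were higher and 2 lower. HOX genes, which mark position along the body axis, had 24 of 33 members positive with a median of 0.33 (camera adjusted p = 0.00677, and adjusted p = 0.882 with an estimated correlation). HOXC10 was at 1.77 ± 0.72 and HOXA9 at 1.28 ± 0.81. The p53 response list had 14 of 15 positive with a median of 0.18 (adjusted p = 0.0108, and adjusted p = 0.821 with an estimated correlation). The cell cycle inhibitor gene CDKN1A was at 0.86 ± 0.74 and BAX at 0.44 ± 0.31. Of 8 beige adipocyte genes 7 were positive, with a median of 0.23 (adjusted p = 0.0364, and adjusted p = 0.809 with an estimated correlation). HOXC9, which the HOX list also holds, was at 1.54 ± 0.87. SHOX2, a transcription factor gene of limb and heart, was at 1.74 ± 0.79 with no more than 0.47 CPM in each library. KLHL13 was at 0.26 ± 0.32 and TNFRSF9 at 0.39 ± 0.53. Hepatic and endodermal genes were lower in 18 of 18, with a median of -0.69 (adjusted p = 0.0272, and adjusted p = 0.821 with an estimated correlation). HNF4A, a liver and gut transcription factor (ENSG00000101076, chromosome 20, 44355700 to 44434596, plus strand), was at 10.9 ± 1.18 CPM on day 50 and 7.5 ± 1.06 CPM on day 60. The plasma protein gene TTR went from 3.97 to 199 CPM within day 50. Cell cycle genes were lower in 26 of 34, with a median of -0.11 (adjusted p = 0.0438, and adjusted p = 0.932 with an estimated correlation). The replication genes MCM4 and MCM3 were at -0.80 ± 0.72 and -0.51 ± 0.57. MKI67, a marker of dividing cells, was at 9.81, 26.0 and 29.3 CPM on day 50 and 11.2, 50.3 and 10.4 CPM on day 60.

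Each of these 5 calls was lost when single libraries were left out. The HOX call ended without day 50 replicate 1 (adjusted p = 0.783 in camera, direction turned) or day 60 replicates 2 or 3 (0.976 and 0.305). The p53 call ended without day 50 replicates 2 or 3 (0.102 and 0.167) or day 60 replicates 1 or 3 (0.518 and 0.707). The beige call ended without any library but day 60 replicate 1, at adjusted p-values from 0.0592 to 0.587. The hepatic call ended without day 50 replicate 1 (0.689), day 50 replicate 3 (0.505, direction turned) or day 60 replicate 3 (0.877). The cell cycle call ended without day 50 replicate 2 (0.467) or, with its direction turned, day 50 replicate 3, day 60 replicate 1 or day 60 replicate 3 (0.592, 0.714 and 0.83). The cell cycle and TCA cycle calls were also lost when libraries were scaled by total count only, both at 0.0932. The beige call was lost when genes were filtered more loosely or more strictly (0.196 and 0.246).

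**Figure D2:**
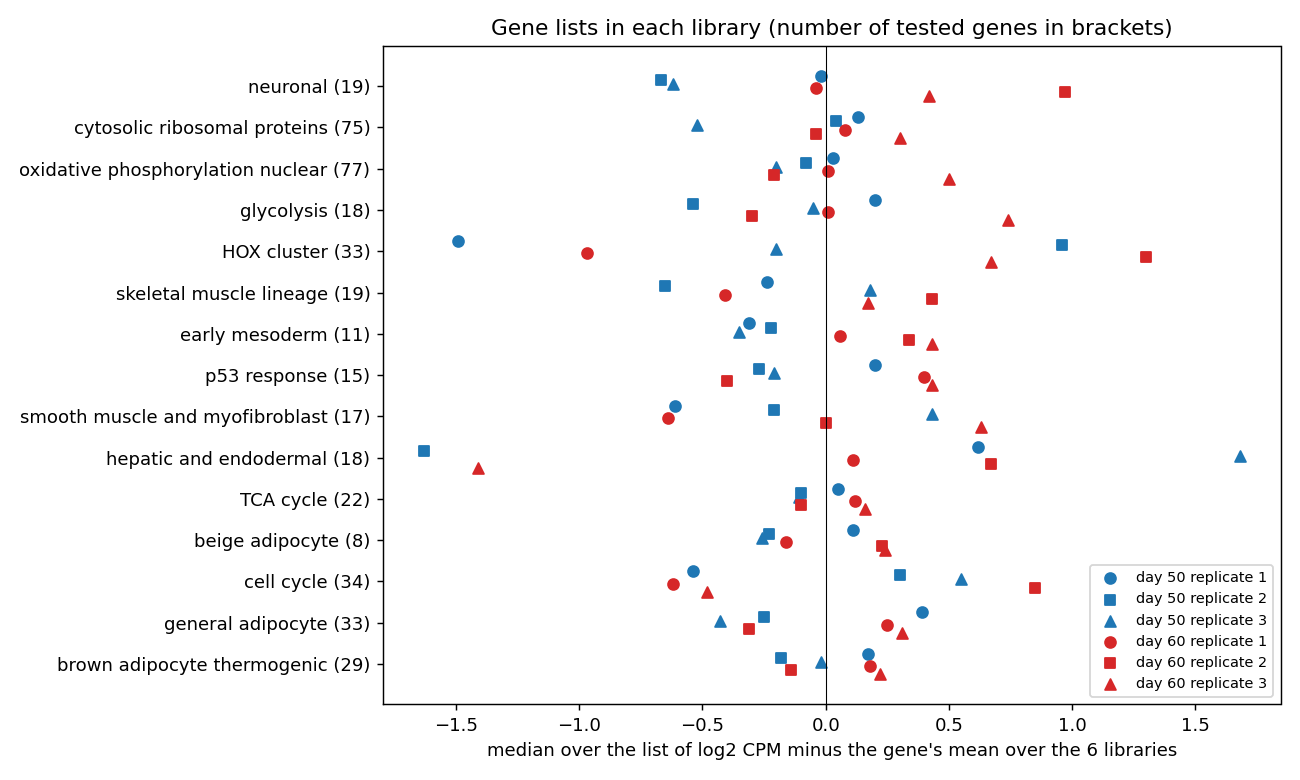
Median of each called list and of both adipocyte lists in each library, as log2 CPM relative to each gene's mean over the 6 libraries, with the number of tested genes in brackets, day 50 in blue and day 60 in red. The hepatic list spreads from -1.63 in day 50 replicate 2 to 1.68 in day 50 replicate 3, and the HOX list from -1.49 in day 50 replicate 1 to 1.30 in day 60 replicate 2.

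Markers of other cell types that were not part of a called list were present at both days. The epithelial keratins KRT8 and KRT19 were at 1115 to 2316 CPM and 427.2 to 1207 CPM over the 6 libraries, and the epithelial list had 10 of 15 members with a positive change (camera adjusted p = 0.56). The endothelial receptor genes KDR and FLT1 were at 592.2 to 1154 CPM and 40.0 to 127.4 CPM (list adjusted p = 0.56). The cardiac list was led by MYL7, at 83.4 to 223.3 CPM, and HAND2, at 67.1 to 205.6 CPM (adjusted p = 0.82). Cartilage and bone genes were led by COL11A1, at 756.3 to 991.9 CPM (adjusted p = 0.56), and the immune list by CD74, at 11.01 to 112.8 CPM (adjusted p = 0.56). The pluripotency factors POU5F1 and NANOG were at no more than 0.14 and 0.24 CPM. LIN28B, an RNA-binding protein gene of fetal and stem cells, was at 6.3 to 39.5 CPM, and that list did not pass (adjusted p = 0.104). The remaining lists did not pass either. Median and mean differed in sign for the inflammatory, neural progenitor, heat shock and cholesterol lists, and camera gave a direction against the median for the brown adipocyte, inflammatory, neural progenitor, BMP and insulin lists.

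The libraries did not separate by day. The first principal component held 51.4% of the variance and placed both replicate 1 libraries and day 60 replicate 3 on one side and the other 3 libraries on the other. The second held 21.2%. Libraries of the same day correlated with r from 0.921 to 0.963 across genes, and libraries of different days with r from 0.926 to 0.993, where genes are not independent replicates. Day 50 replicate 1 and day 60 replicate 1 were the closest pair, with r = 0.993, a BCV of 0.108 and 2.5% of tested genes at least 2-fold apart. The other 14 pairs had BCVs from 0.29 to 0.476. That pair still differed beyond counting noise in 6401 genes, 41.1% of those tested, and was kept as 2 libraries. Without both replicate 1 libraries, an alternative chosen after the data were seen, 0 genes were called by edgeR, with 460 at an unadjusted p under 0.05, and 14 lists passed camera. The hepatic and TCA cycle calls were lost (adjusted p = 0.386 and 0.136), and general adipocyte genes were among 3 lists gained.

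**Figure D3:**
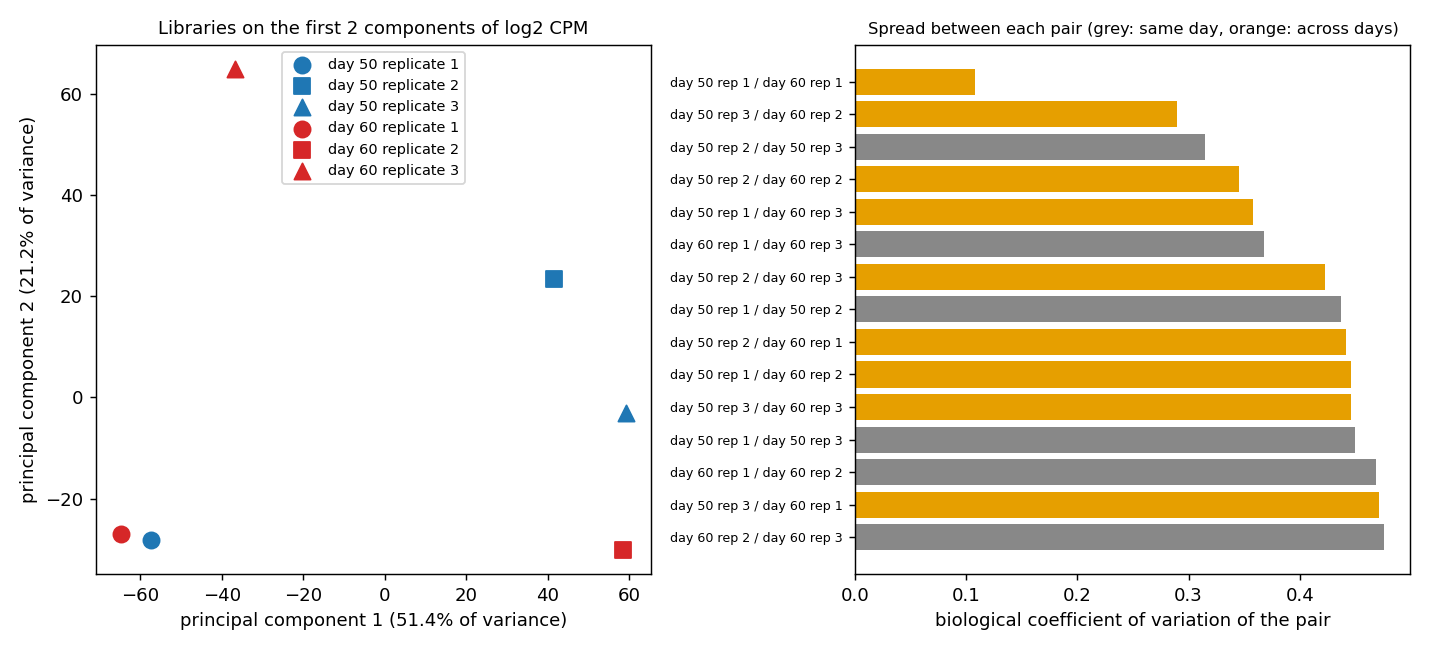
Left, the 6 libraries on the first and second principal components of log2 CPM, with day 50 in blue, day 60 in red and symbols for replicates. Right, the biological coefficient of variation of each of the 15 pairs, same-day pairs in grey and pairs across days in orange; the replicate 1 pair stands at 0.108 and the next pair at 0.29.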

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

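The alternatives were planned, except leaving out both replicate 1 libraries and the other cut-offs for genes on and off, which were chosen after seeing the data. The count of genes called was 0 under every normalization, filter, test, threshold and left-out library that was run, and 41 to 789 genes had an unadjusted p under 0.05. In simulations of this comparison 4-fold changes were called in 49.2% of genes and 2-fold changes in 2.8%, so that most 2-fold changes would be missed at this spread. The simulated libraries lacked the structure across days of the real ones, so the shares may differ for these. With no count filter, which lets in UCP1 and other genes of few reads, 0 genes were called. The count of lists called was 13 and became 0 with camera at an estimated correlation and 0 with fry. It ranged from 2 to 16 when single libraries were left out (2 without day 60 replicate 3, 8 without day 50 replicate 2) and from 11 to 14 under the other settings. Of the called lists, 5 turned direction when a library was left out, and the cause was not tested. Oxidative phosphorylation turned without day 60 replicate 3 (adjusted p = 0.818, leave-one-out range 2.41e-12 to 0.818), as did smooth muscle (0.877, range 1.98e-07 to 0.877). HOX genes turned without day 50 replicate 1 (0.783, range 6.17e-14 to 0.976) and hepatic genes without day 50 replicate 3 (0.505, range 1.61e-20 to 0.877). Cell cycle genes turned without day 50 replicate 3, day 60 replicate 1 or day 60 replicate 3 (0.592, 0.714 and 0.83, range 1.12e-11 to 0.83). Over all lists and alternatives, 65 tests lost a call in the same direction, 28 gained one, 7 of called lists turned direction, and 630 stayed on their side of the threshold, some of them, in lists not called, with the direction turned. The neuronal call was kept in all 15 alternatives other than the estimated correlation and fry. The first component held 57.6% of the variance with the 500 most variable genes and 51.4% with all genes. Of 1124 fits of 63 named genes none passed the threshold and 20, in 12 genes, changed sign, and all 44 marker levels stayed within 1 SD. The replicate numbers did not pair all the libraries. The deviations of same-numbered libraries from their day means correlated at 0.70 for replicate 1, 0.21 for replicate 2 and -0.12 for replicate 3. Day 60 replicate 2 correlated best with day 50 replicate 3 (0.55). The replicate 1 libraries did go together, and the main test does not model that pairing. With a replicate block 0 genes were called (220 at an unadjusted p under 0.05) and 12 lists, the beige list not being among them (adjusted p = 0.0852). The main list test already uses voom weights, so voom was not run as its alternative. Leaving out the mitochondrially encoded genes, all listed at 0, moves nothing and says nothing of stability. Genes on in some libraries and off in the rest numbered 19, and 8 with off below 0.2 CPM.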

Other observations

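The genes and tests of this part were chosen after the values were seen, apart from the tests of cells of another type in replicate 3 on genes 4-fold apart, of day 60 replicate 3 alone, of length and GC content over the called lists, and of other splits of the libraries. Several programs of other tissues differed strongly between libraries without following the day. The fetal liver genes AFP and TF were highest in day 50 replicate 3 and lowest in day 50 replicate 2 and day 60 replicate 3. AFP, the fetal serum protein, was at 834.7, 89.8 and 2590 CPM in day 50 replicates 1, 2 and 3 and at 504.3, 1275 and 48.2 CPM in day 60 replicates 1, 2 and 3. The transferrin gene TF was at 79.5, 2.02 and 382.9 CPM and at 41.8, 137.1 and 6.07 CPM. Keratins of stratified epithelium took another order, as KRT5 was at 146.6, 43.4 and 6.51 CPM on day 50 and 191.4, 1.64 and 1135 CPM on day 60, and KRT17 at 260, 66.2 and 4.89 CPM and 355.9, 4.97 and 983.6 CPM. ITLN1, a lectin of mesothelium and omental fat, was at 336.4, 5508 and 1720 CPM and at 264.3, 805.3 and 2297 CPM. The cardiomyocyte list had medians of -0.37, -0.50 and 0.66 relative to the mean of the libraries on day 50 and of -0.97, 0.59 and 0.40 on day 60. Its members did not share an order, as MYL7 was highest in day 50 replicate 1, at 223.3 CPM, HAND2 in day 60 replicate 2, at 205.6 CPM, and MYH6 in day 60 replicate 3, at 84.1 CPM.

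HOX genes, the lipid droplet gene PLIN2 and the general adipocyte list also differed by library. The HOX list had medians of -1.49 and -0.97 relative to the mean of the libraries in the replicate 1 libraries of days 50 and 60, of 0.96 and 1.30 in the replicate 2 libraries, and of -0.20 and 0.67 in the replicate 3 libraries. PLIN2 was at 1727, 604.7 and 552.8 CPM on day 50 and 1580, 780.9 and 1634 CPM on day 60. The adipocyte gene FABP4 took another order, at 0.10, 6.15 and 2.87 CPM on day 50 and 0.27, 0.85 and 3.46 CPM on day 60. The general adipocyte list had medians of 0.39, 0.25 and 0.31 in day 50 replicate 1, day 60 replicate 1 and day 60 replicate 3 and of -0.25, -0.43 and -0.31 in the other 3 libraries. The cell cycle list was opposite, at -0.54, -0.62 and -0.48 in the first 3 and 0.30, 0.55 and 0.85 in the others. SLC15A4, a lysosomal transporter gene on chromosome 12 (128793191 to 128823983, minus strand, GRCh38), had 637 and 1140 reads in the replicate 3 libraries and 1, 0, 0 and 0 reads in the others. LYNX1, THEM6 and SLITRK4 went the same way, LYNX1 and THEM6 lying near each other on chromosome 8. ZNF558, a zinc finger gene on chromosome 19, was off in replicate 3, at 0 and 0.265 CPM, and at 19.5 to 30.9 CPM elsewhere.

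The libraries of replicate 1 were far closer to each other across days than any other pair. A single library deposited under both days is argued against by the 41.1% of tested genes that differed beyond counting noise. A culture state shared by libraries with one replicate number may account for the pair, but the other numbers gave no such closeness, the lowest correlation of deviations being -0.12, and 6 genes still parted same-numbered libraries from the rest. This stays open. Whether both replicate 1 libraries came from a single differentiation is not stated in the labels used here.

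A small set of genes was on, above 5 CPM, in some libraries and off, under 0.5 CPM, in the rest. There were 19 such genes, 0 followed the day, and 10 parted a pair of libraries from the other 4, among them 6 that parted libraries with the same number, where 3 of the 15 possible pairs share a number. For ZNF558, dilution by added cells of another type in replicate 3 would have to leave only 1.36% of its lowest level elsewhere. COL1A1 differed at most 1.54-fold between replicate 3 and the other libraries, which argues against such dilution for this gene. The gene was picked for being off in replicate 3, so a low remainder was fixed in advance and is no separate test. For the genes that were on, 8 genes lay at least 4-fold apart in both replicate 3 libraries, 5 of them higher, against a median of 1.5 and a highest of 55 over the other 14 pairs, and added cells stay open. A candidate explanation, mainly for replicate 3, is that libraries of one number descend from the same starting cells with a gene silenced or active. The labelled numbers held 6 of these genes (5 in replicate 3, 1 in replicate 1 and 0 in replicate 2). The best of the 5 other ways to match the days held 5. This cannot decide for replicate 3, because a matching with 5 genes keeps the replicate 3 pair and its genes. OLFM4, CEACAM5, AGR2 and KRT20 parted libraries of different numbers, day 50 replicate 3 and day 60 replicate 2. Further, 6 matchings are too few for a share under 0.05. With an off limit of 0.2 CPM, 2 of 5 pair-parting genes parted same-numbered libraries with on above 5 CPM (8 genes in all). With on above 2 CPM they were 4 of 7 (16 in all). OLFM4, CEACAM5 and AGR2 still parted the other pair at both limits.

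Of the 11 lists called higher at day 60, all but 2 may rest on day 60 replicate 3. Without it only the neuronal and ribosomal protein lists were still called. The beige, early mesoderm, skeletal muscle, smooth muscle and HOX calls were also lost without day 60 replicate 2, so they did not rest on replicate 3 alone. Transcript length and GC content, with which the gene statistic correlated across genes at rho = -0.254 and 0.303, are argued against as the whole cause for the 9 lists called after that trend was removed, 8 of them called before and after and the beige list after only (adjusted p = 0.0702 before and 0.0448 after in limma, mean statistic 0.623 and 0.617, SE 0.303); the skeletal muscle list stayed called but moved most of the 9 (adjusted p = 0.00262 and 0.0371, mean statistic 0.676 and 0.44, SE 0.224). All of these calls used the preset correlation, so they show only that a shift of the lists was left beside the fitted trend. The mean statistic fell for oxidative phosphorylation (0.735 and 0.551) and ribosomal protein genes (0.75 and 0.581) and held for neuronal genes (1.387 and 1.392). For early mesoderm and HOX genes length and GC content cannot be told apart from a change. Early mesoderm lost its call on removal (mean statistic 0.674 before and 0.41 after, SE 0.171), and HOX was called neither before nor after (0.36 and 0.12, SE 0.124). The 10 splits of the 6 libraries are too few for a share under 0.05; 7 of them, the real one included, called at least 13 lists, the real count (highest other 20), and for genes the count of 10 is fixed by the real count of 0 and says nothing of chance (highest other 1958). The split with 1958 genes set both replicate 1 libraries and day 60 replicate 3 against the rest, which points to a structure of the samples other than day, and a change over the days themselves stays open and untested apart from it.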
